A study of Mus musculus with 10 samples.

How the data were processed

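RNA from sorted splenic memory B cells of 5 wild type and 5 Zbtb32 knockout mice was extracted with a column kit, amplified, labelled with biotin and hybridised to 10 one-colour Affymetrix arrays, per the labels' protocols. The deposited table holds 1 log2 signal per probe set and array, made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes. Their versions, the genome build and the annotation are not given in the sources used here. RMA corrects background, normalizes between arrays and summarises probes on the log2 scale. The column medians lay between 4.00 and 4.22 and all values between 0.71 and 13.7, so the values were on the log2 scale and not centred per gene. The columns did not have identical distributions. Scanner files and detection calls were not used here, so no bound for dim probe sets is given, and fold changes of low signals are compressed. No slide or scan batch is given in the labels.

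Of 35556 rows, 21789 were paired with 1 gene, 1621 with several genes and 12146 with none in the platform annotation table used. Rows of the first kind were tested, and rows with several genes were neither named nor tested. Cd19 was paired with no row, while 3 of 12 immunoglobulin constant genes were measured. Of the 19938 genes, 999 had several rows and were represented by the row with the highest mean over all arrays. Gene identifiers matched a GRCm38.p6 annotation for 19856 genes. That annotation was used for names and for which genes lie near Zbtb32, and no coordinates are printed because the files name no build. No column of the table was left unused.

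Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) on the deposited log2 values, with genotype as the only term, all 10 arrays and a Benjamini-Hochberg adjusted p of 0.05, two-sided. Gene lists were tested with camera at a preset correlation of 0.01 and adjusted over the 38 lists with at least 3 measured genes. Each list was tested again with an estimated correlation and by an exact two-sided permutation test of its mean per array. The 39 lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Of 1033 list entries 917 were measured. The rule names Zbtb32, up to 12 genes per direction with the largest change among those past the threshold with groups that do not overlap, or else the 6 with the smallest p in that direction. It adds the members of each list with the smallest p, 4 for a list past the threshold and 2 or fewer for the others, as well as genes of the gate, sex and neighbour checks. Predicted genes and immunoglobulin or T cell receptor variable segments were passed over in the first part.

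Genotypes share replicate numbers, and the labels do not say whether a number marks a shared day or litter. The deviations of same-numbered arrays from their group means correlated at 0.319, 0.517, 0.247, 0.301 and 0.312 for numbers 1 to 5, above 0.1 in every pair, so the numbers were treated as pairing the samples and the fit with the number as a block is given beside results it changes. This pairing comes from the data. It was mostly a division of numbers 1 and 2 from 3 to 5, since deviations of arrays 3 to 5 correlated at 0.172 to 0.362 between genotypes whatever their number, and 5 of the 10 arrays correlated best with their own number. Correlations between arrays over all genes were 0.986 to 0.992 among arrays 3 to 5 and 0.959 to 0.978 among arrays 1 and 2. No arrays held identical values, and each was counted as 1 replicate.

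The fit was tested on simulated data with the real means and spreads of the 19938 genes, with 100 genes changed by each of 2 sizes. It recovered 78% of changes of 1 log2 unit and 98% of changes of 2 log2 units, and 7 of 183 calls were unchanged genes. A list of 38 genes moved by 0.5 was the only list called. Genes and arrays were simulated as independent, without the division of numbers 1 and 2 from 3 to 5. In the real arrays the estimated correlation within that S phase list was 0.43. The simulation therefore cannot show how often camera calls unmoved lists in these arrays. Alternatives were other priors, array weights, other normalizations, filters on dim genes, the mean of a gene's rows, all rows of the table, other thresholds, the replicate block, covariates for sex, other cells, plasma cells and immediate early genes, and leaving out each array. Restricting the fit to arrays 3 to 5, taking numbers 1 and 2 against 3 to 5 as a covariate, an estimated correlation in these fits and with the block, and a paired fit of the G2/M list mean were added after the data were seen. For genes near Zbtb32 the unadjusted p of 0.01 was set once the results of single genes were known and before the neighbours were counted, and the unadjusted p of 0.05, arrays 3 to 5 and the block were added after that count.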

Results

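Transcript levels were measured on Affymetrix arrays in resting memory B cells sorted from the spleens of unimmunized mice. Memory B cells are long-lived B lymphocytes that persist after an earlier immune response. The sort kept cells carrying CD19, CD80 and CCR6 and lacking surface IgM and IgD. The design has 2 groups, wild type and Zbtb32 knockout, with 5 arrays each that the series describes as biological replicates. Zbtb32 is a zinc finger transcriptional repressor of the BTB family. The comparison asks which transcripts depend on Zbtb32 in memory B cells before any recall stimulus. Values are RMA signals on the log2 scale. After probe sets were paired with genes, 19938 genes were tested. All differences are knockout minus wild type, and an array is named by its genotype and the number in its label. The number of arrays, not a read depth, limits the precision, and the median standard error of a gene's difference was 0.15 log2 units.

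Zbtb32 was the only gene past the threshold. Its signal was 7.93 ± 0.68 (SD, n = 5) in wild type and 5.19 ± 0.55 (SD, n = 5) in knockout arrays, so that it fell by 2.73 on the log2 scale (SE 0.33), or was 6.65-fold lower. All 5 knockout arrays, between 4.61 and 5.85, lay below all 5 wild type arrays, between 7.11 and 8.99. The adjusted p from limma was 0.0471, and the exact two-sided permutation test gave p = 0.00794, the smallest that 5 arrays against 5 allow. That test ignores the replicate numbers, and an exact sign-flip test of 5 pairs allows no p below 0.0625. The gene is represented by 1 probe set, and whether its probes lie in the deleted part is not given in the sources used here. The difference was −2.04 (SE 0.22) in arrays numbered 3 to 5 and −3.77 in arrays numbered 1 and 2, and the difference between these effects was −1.72 (SE 0.48). With the replicate number as a block the fall was of the same size, but the limma adjusted p was 0.188, and over all settings tried the adjusted p lay between 0.0178 and 0.203. The limma adjusted p was 0.113, 0.203 and 0.130 without wild type 2, 3 and 5, and 0.20, 0.187, 0.0662, 0.173 and 0.176 without knockout 1 to 5, with differences from −2.90 to −2.59.

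**Figure D1:**
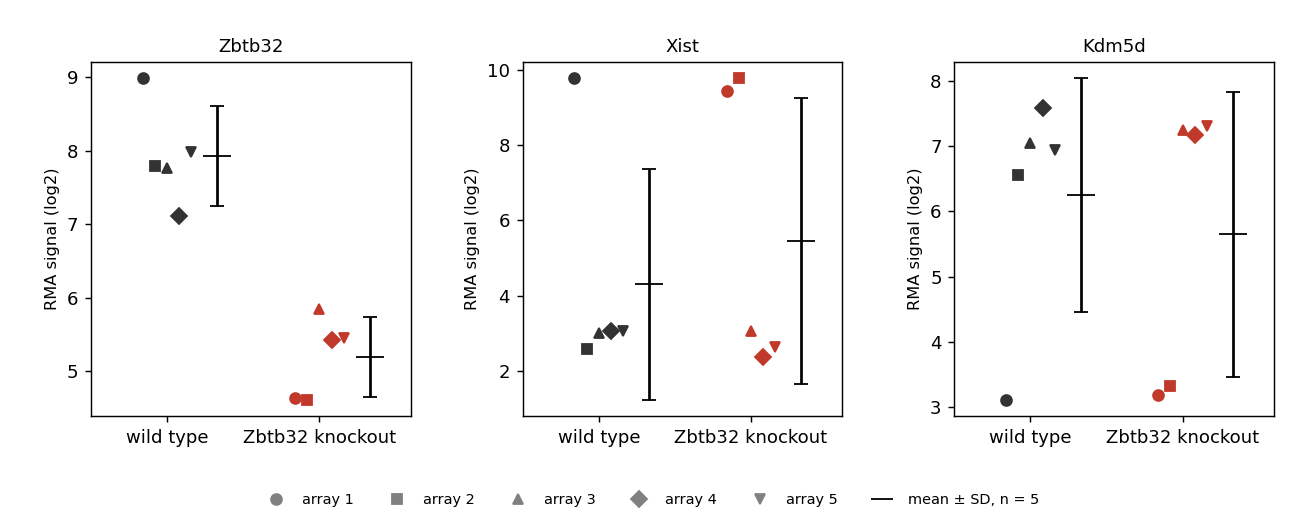
RMA signal (log2, vertical axes) of Zbtb32, Xist and Kdm5d in each of the 10 arrays, by genotype (horizontal axes); symbols give the replicate number, and the horizontal bars with whiskers are the mean and SD of 5 arrays. Zbtb32 is lower in all 5 knockout arrays, while Xist is at 9.45 or above in wild type 1, knockout 1 and knockout 2 and at 3.07 or below in the other arrays.

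Markers of other splenic cells separated arrays by replicate number, not by genotype. S100a8, a calcium-binding protein abundant in neutrophils, had signals of 10.9 and 11.7 in wild type 1 and 2 and of 10.8 and 10.4 in knockout 1 and 2. In arrays numbered 3 to 5 it lay between 2.56 and 4.36. The mean of 16 neutrophil markers was at least 5.21 in the 4 arrays numbered 1 and 2 and at most 3.39 in the other 6 arrays. For T cell markers the bounds were 5.10 and 4.28, for erythroid and platelet markers 4.13 and 3.64, and for myeloid and dendritic cell markers 5.47 and 5.06. Of the 16 neutrophil, 18 T cell, 11 erythroid and platelet and 28 myeloid markers, 2, 6, 1 and 17 were above the median gene in arrays 3 to 5, and 0, 2, 0 and 6 stood in another list. NK cell markers overlapped between these arrays, as did stromal and endothelial markers. Wild type 2 had the lowest signals of the sort markers, 6.37 for Cd80 against 7.54 ± 0.70 (SD, n = 5) over all wild type arrays and 7.70 for Ccr6 against 8.90 ± 0.71 (SD, n = 5). Ighm, which encodes the IgM heavy chain, ranged from 7.83 to 10.5 although the gate excluded surface IgM. It was at 9.89 or above in the 4 arrays numbered 1 and 2 and at 9.51 or below in the other 6. Between genotypes, limma's camera gave adjusted p = 0.154 for neutrophil, 0.505 for T cell, 0.550 for myeloid and dendritic cell, 0.472 for erythroid and platelet, 0.529 for NK cell and 0.216 for stromal and endothelial markers. With the replicate number as a block, 3 of these 6 lists were lower in knockout arrays. Their adjusted p was 0.0297 for neutrophil, 0.0233 for T cell and 0.0155 for erythroid and platelet markers. With the block, adjusted p = 0.433, 0.563 and 0.336 with an estimated correlation. Members with the smallest p were Mmp9 (−0.40) and Mpo (−0.39) for neutrophils, Cd6 (−0.37) and Cd2 (0.14) for T cells, and Gp9 (−0.41) and Epb42 (0.37) for erythroid cells and platelets. For myeloid and dendritic cells they were Flt3 (−0.43) and Siglech (−0.67), for NK cells Eomes (0.21) and Klrg1 (−0.23) and for stroma Dcn (−0.31) and Mgp (−0.29), and none passed. Siglech differed by −0.83 to −0.13 with 1 array left out. For NK cell markers the mean difference was −0.04 and the median 0.06, so that the direction was not settled.

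**Figure D2:**
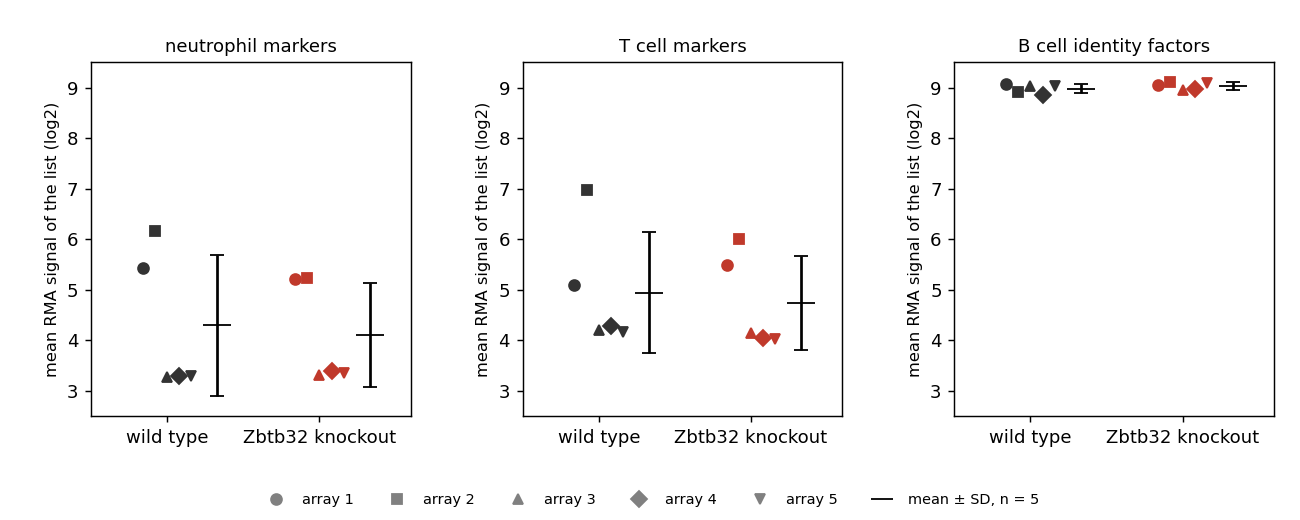
Mean RMA signal (log2, vertical axes) of the neutrophil, T cell and B cell identity lists in each array by genotype (horizontal axes); symbols give the replicate number, and bars with whiskers are the mean and SD of 5 arrays. Arrays numbered 1 and 2 of both genotypes lie above arrays 3 to 5 for neutrophil and T cell markers, and all 10 lie between 8.86 and 9.11 for B cell identity factors.

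The arrays also differed in sex-linked transcripts. Xist, the RNA that coats the inactive X chromosome, was high in wild type 1, knockout 1 and knockout 2, where the Y-linked Kdm5d was at 3.32 or below. In the other 7 arrays Kdm5d was between 6.55 and 7.58. Uty and Eif2s3y, also Y-linked, followed Kdm5d, and the list of Y-linked genes gave a camera adjusted p of 0.515 between genotypes.

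Apart from Zbtb32 no gene passed an adjusted p of 0.05 in limma, and none rose. At an unadjusted p of 0.05 there were 388 genes higher and 529 lower in knockout arrays, 917 in all against 997 expected by chance. The strongest candidate for a rise was Pmm2, a phosphomannomutase needed for N-glycosylation. It was at 6.53 ± 0.11 (SD, n = 5) in wild type and 7.34 ± 0.075 (SD, n = 5) in knockout arrays, a difference of 0.81 (SE 0.11, limma adjusted p = 0.106) in the same direction in all 5 same-numbered pairs. Pmm2 passed with array weights (adjusted p = 0.0441), without an intensity trend (0.0293) and among genes brighter than the median (0.0386). It did not pass with the replicate block (limma adjusted p = 0.523) or in arrays 3 to 5 (0.256). Nor did it pass with any 1 array left out (0.161 to 0.621). The other genes with the smallest p on this side did not pass, at adjusted p of 0.807 for Akr1e1 and 0.953 for the rest. Their differences were 0.95 for the aldo-keto reductase Akr1e1, 0.48 for Gmfg, an actin regulator of blood cells, 0.97 for Ighg3, the IgG3 heavy chain, 0.65 for Atpsckmt and 0.56 for Vipas39. On the lower side the centrosomal gene Cep89 differed by −0.86 (SE 0.13, adjusted p = 0.213), from 5.67 ± 0.19 to 4.81 ± 0.15 (SD, n = 5 each). Cdk5rap1, a tRNA-modifying enzyme, differed by −1.19 (SE 0.24, adjusted p = 0.953). The olfactory receptors Olfr544 and Olfr16 differed by −0.78 and −0.48 and the microRNA gene Mir16-1 by −0.59, all at mean signals of 2.97 or less, below the median of 4.30 over all genes tested.

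Of 38 gene lists tested, 10 ranked higher and 0 lower in knockout arrays by camera with its preset correlation of 0.01. With an estimated correlation 0 of the 38 passed, and the smallest adjusted p was 0.110. The 2 cell cycle lists were among the 10. All 35 measured genes of the G2/M list, which act in mitosis, had higher means in knockout arrays, with a mean difference of 0.42 (camera adjusted p = 2.07e-06, and adjusted p = 0.699 with an estimated correlation). With the block of replicate numbers the camera adjusted p was 9.65e-17, and adjusted p = 0.336 with an estimated correlation. None passed alone, over all genes or adjusted over the list alone. Ndc80 differed by 0.59 (SE 0.25), Cenpf by 0.68 (SE 0.32), Cenpe by 0.74 (SE 0.36) and Kif20b by 0.33 (SE 0.20). The list mean was 5.18 ± 0.67 (SD, n = 5) in wild type and 5.60 ± 0.83 (SD, n = 5) in knockout arrays, and it was higher in knockout in all 5 same-numbered pairs, by 0.066 to 1.04. It was also higher in arrays numbered 1 and 2, where neutrophil and T cell markers were high. The difference was 0.71 within those arrays and 0.22 within arrays 3 to 5. It was 0.69 without wild type 1, 0.15 without knockout 1 and 0.23 without knockout 2. Of 38 measured S phase genes, 28 were higher and 10 lower, with a mean difference of 0.17 (camera adjusted p = 0.00599, and adjusted p = 0.707 with an estimated correlation). The S phase mean was also higher in all 4 arrays numbered 1 and 2, at 5.46 or above against at most 5.40, and its difference was 0.29 within them and 0.086 within arrays 3 to 5. The S phase difference was 0.28 without wild type 1. Without wild type 3 or 4 or knockout 1 or 2 it was 0.11, 0.12, 0.050 and 0.10, at adjusted p of 0.147, 0.0965, 0.282 and 0.188. The cyclin gene Ccne1, which like Zbtb32 is on chromosome 7, differed by 0.72 (SE 0.24). Uhrf1 differed by 0.55, the helicase subunit Mcm3 by 0.63 and the primase Prim1 by 0.33. Cell cycle inhibitors did not differ as a list (camera adjusted p = 0.744), with values of −0.39 for Gadd45a and 0.40 for Cdkn2d.

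Lists of metabolism and protein handling made up a second group. Of 20 measured cholesterol synthesis genes, 17 were higher in knockout arrays, with a mean difference of 0.23 (camera adjusted p = 1.45e-04, and adjusted p = 0.110 with an estimated correlation). Cyp51 differed by 0.53 (SE 0.19), Sqle, a squalene epoxidase, by 0.66 (SE 0.25), Srebf2, the transcription factor of the pathway, by 0.30 (SE 0.13) and Ebp by 0.45 (SE 0.23). The list mean was 5.78 ± 0.097 (SD, n = 5) in wild type arrays, and it was higher in knockout in all 5 pairs, by 0.042 to 0.39. Its exact two-sided permutation p was 0.0159, the smallest of the 39 lists, and 0.619 after adjustment. Subunits of oxidative phosphorylation were higher for 63 of 72 genes, by a mean of only 0.11 and in 3 of 5 pairs (camera adjusted p = 2.26e-05, and adjusted p = 0.699 with an estimated correlation). The list mean was at 9.03 or above in the 4 arrays numbered 1 and 2 and at most 8.94 in the other 6, the same division as for neutrophil and T cell markers. Their difference was 0.031 without wild type 4 (adjusted p = 0.168), 0.055 without knockout 1 and 0.17 without wild type 2. The ATP synthase subunits Atp5j and Atp5g2 differed by 0.25 and 0.28, Ndufa4 by 0.20 and Ndufv2 by 0.30. The mTORC1 and MYC target list was higher for 30 of 37 genes, by a mean of 0.09 (adjusted p = 0.00312, and adjusted p = 0.516 with an estimated correlation), with Mthfd2 at 0.52, Hspd1 at 0.21, Ddx21 at 0.23 and Slc7a1 at 0.27. Its difference was 0.16 in arrays numbered 1 and 2 and 0.050 in arrays 3 to 5. The mitochondrial ribosome and biogenesis list was higher for 29 of 39 genes and the unfolded protein response list for 22 of 31, by a mean of 0.07 each (adjusted p = 0.0382 for both). For these lists adjusted p = 0.699 and 0.675 with an estimated correlation. In the first, Tomm20, Tfb1m and Mrps14 differed by 0.22, 0.39 and 0.24 and Mrps12 by −0.70. In the second, Edem2 and Canx differed by 0.37 and 0.18, and the stress genes Atf3 and Trib3 by −0.43 and −0.24. The mitochondrial list was not past the threshold without wild type 3 or 4 or knockout 1, 2 or 5 (0.068, 0.019, 0.038, 0.067 and 0.060) and was at 0.13 without knockout 3. Its difference was 0.038 in arrays numbered 1 and 2 and 0.099 in arrays 3 to 5. The unfolded protein response list was not past it without wild type 3 or 4 or knockout 2 (0.042, 0.032 and 0.021). Of its genes 8 are also in the plasma cell list, and the means of the 2 lists correlated at 0.912 over the 10 arrays. Both were highest in knockout 2, at 7.38 and 7.28, and with the plasma cell mean as a covariate the difference was 0.040 (adjusted p = 0.173). That covariate contains the 8 shared genes. Without the shared genes the correlation was 0.799, and the unfolded protein response difference, without a covariate, was 0.078. No gene of these metabolism and protein handling lists passed alone, over all genes or adjusted over the list alone.

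Lists of B cell states gave small differences. Germinal centre genes were higher for 11 of 16, by a mean of 0.23 and in all 5 pairs (camera adjusted p = 0.00578, and adjusted p = 0.516 with an estimated correlation). They were not past the threshold without wild type 4 (0.19, adjusted p = 0.0586) or knockout 1 (0.14, adjusted p = 0.0750). The difference was 0.35 in arrays numbered 1 and 2 and 0.15 in arrays 3 to 5. Polh, a polymerase of somatic hypermutation, differed by 0.48 (SE 0.18), Cd83 by 0.41 (SE 0.18), Fas by 0.43 (SE 0.23) and Neil1 by 0.35 (SE 0.23). With 1 array left out, Fas differed by 0.18 to 0.56 and Neil1 by 0.16 to 0.49. Memory B cell genes were higher for 19 of 24, by a mean of 0.11 (adjusted p = 0.0382, and adjusted p = 0.523 with an estimated correlation), with Tox at 0.81, Cd44 at 0.26 and Bhlhe41 at 0.41 but Cd27 at −0.78. Leaving out 1 array gave −1.03 to −0.25 for Cd27 and 0.13 to 0.53 for Bhlhe41. Memory genes were not past the threshold without wild type 2, 3 or 4 or knockout 1, 2 or 5 (0.053, 0.12, 0.10, 0.097, 0.12 and 0.10), at adjusted p from 0.0661 to 0.334. B cell receptor signalling genes were higher for 22 of 26, by a mean of 0.06 (adjusted p = 0.0382, and adjusted p = 0.516 with an estimated correlation), with Ptpn6 at 0.20, Rasgrp3 at 0.37 and Cd79b at 0.08 but the complement receptor Cr2 at −0.44. Receptor signalling genes were not past it without wild type 2, 3 or 4 or knockout 2, 3 or 5 (0.029, 0.063, 0.071, 0.065, 0.049 and 0.045), at adjusted p from 0.0505 to 0.167. No gene of these lists passed alone, over all genes or adjusted over the list alone. Other B cell lists did not pass. The adjusted p was 0.0710 for identity factors, 0.0741 for plasma cell genes, 0.104 for marginal zone genes, 0.507 for B-1 cell genes and 0.599 for naive follicular genes. In the blocked fit identity factors (0.0410) and plasma cell genes (0.0249) passed as higher and marginal zone genes (0.0233) as lower. With the block, adjusted p = 0.466, 0.528 and 0.356 with an estimated correlation. Examples are Irf8 at 0.27, Mzb1 at 0.36 and Slamf7 at 0.22, Myof at −0.58, Cd300lf at −0.34, and Satb1 at −0.35 with Il4ra at 0.17. With 1 array left out, Satb1 differed by −0.47 to −0.062 and Mzb1 by 0.12 to 0.48. The B-1 list holds Zbtb32, its only member past the threshold, and 9 of its 16 measured genes were lower. Among 3 measured immunoglobulin constant genes (adjusted p = 0.0741), Ighg3, at 3.38 and 4.36 in wild type and knockout, rose when adjusted over the list alone, and Ighm differed by 0.13 (SE 0.51).

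Lists fixed for what is known of Zbtb32 did not pass in the unblocked fit of all arrays. The MHC class II and Ciita list, which also holds Cd40, Cd80, Cd86, Ctss, Ifi30 and Marchf1, was higher for 10 of 15 genes (adjusted p = 0.0619), with H2-Eb2 at 0.31 and H2-DMa at 0.26. This list passed as higher with the replicate number as a block (adjusted p = 0.0316, and adjusted p = 0.336 with an estimated correlation). It also passed in arrays 3 to 5 (adjusted p = 0.00745, and adjusted p = 0.380 with an estimated correlation). Cytokine and Gata3 targets reported for Zbtb32 were lower for 7 of 10 (adjusted p = 0.608), with Il5 at −0.13 and Tnf at 0.23. Immune response lists gave adjusted p = 0.0691 for type I interferon genes, 0.529 for NF-kB genes and 0.154 for the Toll-like receptor pathway. With the block type I interferon genes passed as higher (adjusted p = 0.0316, and adjusted p = 0.336 with an estimated correlation). Dhx58 and Parp9 differed by 0.39 and 0.32, Nfkbid by −0.64, and Tlr9 and Tirap by 0.38 and 0.41. Survival genes (0.159, Tnfrsf13c at 0.17), homing genes (0.348, Itgb7 at 0.37), glycolysis (0.529, Pfkp at 0.25 and Pdk1 at −0.30), fatty acid oxidation (0.0741, Echs1 at 0.35 and Cpt2 at 0.44) and autophagy and lysosome genes (0.154, Map1lc3a at −0.38 and Gabarapl2 at 0.32) did not pass. Nor did lists that bear on RNA handling, at 0.529 for immediate early genes (Egr2 at 0.59), 0.20 for ribosomal proteins (Rpl28 at 0.13 and Rps10 at 0.10) and 0.187 for histones (H1f2 at −0.41 and H2ac8 at 0.24). Histone genes had means of 6.68 or above in the 4 arrays numbered 1 and 2 and of at most 5.73 in the other 6. Immunoglobulin constant (7.32 against 7.26), glycolysis (6.56 against 6.52), homing (6.93 against 6.88) and autophagy and lysosome genes (6.67 against 6.59) were divided in the same way. In arrays 3 to 5 all 3 lists on RNA handling passed as higher in knockout, at adjusted p of 0.0271 for immediate early, 0.00403 for ribosomal protein and 0.00335 for histone genes. There adjusted p = 0.455, 0.455 and 0.380 with an estimated correlation. With the block histones passed (adjusted p = 0.0208, and adjusted p = 0.382 with an estimated correlation).

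**Figure D3:**
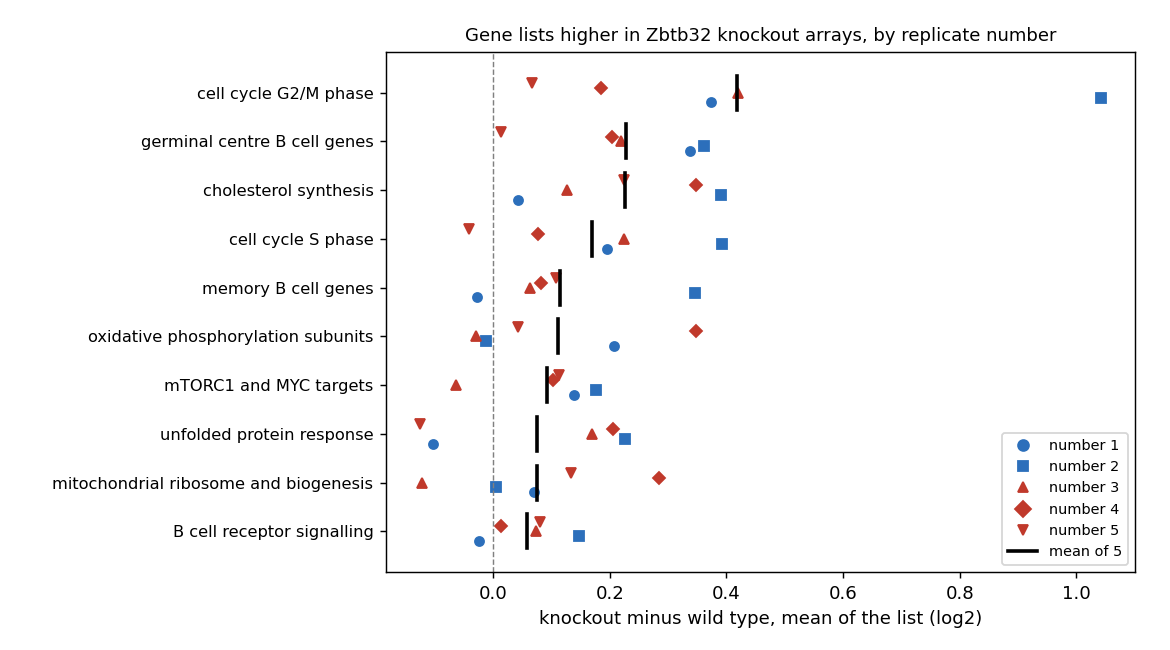
Difference of the list mean between knockout and wild type arrays of the same number (log2, horizontal axis) for the 10 lists that ranked higher in knockout arrays (vertical axis); blue symbols are numbers 1 and 2, red symbols numbers 3 to 5, and black bars the mean of 5. G2/M, germinal centre and cholesterol synthesis genes are above 0 in all 5 pairs, and G2/M reaches 1.04 in pair 2.

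The list calls depended on how dependence between genes and arrays was treated. No list passed an adjusted p of 0.05 with an estimated correlation, and 1 had an unadjusted p under 0.05, cholesterol synthesis at 0.00289. With the replicate number as a block, 19 lists passed, among them all 10 of the unblocked fit, and 0 passed with an estimated correlation. A second quantile normalization left 6 lists, 5 higher and 1 lower, without memory, receptor signalling, mTORC1 and MYC, mitochondrial and unfolded protein response genes. With the plasma cell mean as a covariate S phase (0.12), mitochondrial (0.057, adjusted p = 0.0872) and unfolded protein response genes did not pass. With the sex or the immediate early covariate these 3 lists, memory and receptor signalling genes did not pass. Among genes brighter than the median only the G2/M and cholesterol lists of the 10 passed. The G2/M difference was 0.18 with the sex covariate, 0.22 with the immediate early covariate and 0.27 with array weights. Leaving out wild type 1, 2, 3 or 4 gave 18, 19, 5 and 3 lists. In arrays 3 to 5 alone 16 lists passed, 6 of them among the 10, and 0 with an estimated correlation. The others were the MHC class II list and the 3 RNA handling lists, immunoglobulin constant (0.00206), plasma cell (0.00311), autophagy and lysosome (0.0183) and type I interferon genes (0.0439) as higher, and marginal zone genes (0.0120) and T cell markers (0.0263) as lower. For these last 6 lists adjusted p = 0.380, 0.461, 0.380, 0.380, 0.455 and 0.380 with an estimated correlation. Of the lists above, memory B cell, receptor signalling, S phase and mTORC1 and MYC genes were not past the threshold in arrays 3 to 5, at adjusted p of 0.123, 0.0656, 0.0690 and 0.123.

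Genes close to Zbtb32 on chromosome 7 were compared with all others, because a targeted allele carries flanking DNA of the embryonic stem cells it was made in. Of 283 genes within 10 Mb of Zbtb32 in the GRCm38.p6 annotation, Zbtb32 left out, 0 passed the adjusted p, as did 0 of the 19654 other genes. At an unadjusted limma p of 0.01, 5 of the 283 (1.77%) and 148 of the others (0.753%) passed, an odds ratio of 2.37 (95% confidence interval 0.753 to 5.72, two-sided Fisher's exact p = 0.0674). The 5 were Cep89 at −0.86, Alkbh6 at −0.68, Zfp27 at −0.65, Gmfg at 0.48 and Pepd at 0.93. With the replicate number as a block 11 of the 283 passed, with an odds ratio of 3.14 (1.53 to 5.80, Fisher's exact p = 0.00132). In arrays 3 to 5 it was 8 of 283, with an odds ratio of 2.38 (Fisher's exact p = 0.0241). At an unadjusted p of 0.05 in all arrays, 20 of the 283 (7.07%) and 896 of the others (4.56%) passed. The odds ratio there was 1.59 (0.952 to 2.52, Fisher's exact p = 0.0606). The fixed list of 58 measured neighbours did not pass as a set (camera adjusted p = 0.216), with Sbsn at −0.42. Ccne1, Nfkbid and Mrps12, named above as members of other lists, are among the named genes on chromosome 7. Whether flanking DNA bears on their differences was not tested. Genes in one region are not independent, so these p-values are too small.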

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

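The tests of array structure, arrays 3 to 5 as a subset, the paired fits of G2/M and erythroid means and the tests of genes near Zbtb32 at an unadjusted p were chosen after the result was seen, although the p of 0.01 was set before the neighbours were counted. The G2/M covariate test was set before its own result. Within groups of 5 arrays, 33 of 306 sets of values had 1 array further from the others than Dixon's 95% limit allows, against about 15 expected by chance. The sets hold genes chosen by their p and are not independent, since the sex-linked genes flag the same array together. The 2 counts therefore do not test for an excess. Wild type 2 was the odd array in 15 of the 33 sets. Among genes it stood at 8.34 for Satb1 and, at the low end, 8.34 for Rasgrp3, 4.99 for Neil1 and 4.86 for Ndc80. It was high for Cd6 (6.26), Siglech (6.62), Mmp9 (4.22), Mpo (4.65) and Tyrobp (10.88). Its list means were high for marginal zone genes (7.18), myeloid and dendritic cell markers (7.53), NK cell markers (4.39), type I interferon genes (6.45) and cytokine targets (4.91), and low for receptor signalling (8.39). Knockout 2 stood at 8.63 for H2-Eb2 and 5.74 for Echs1, with high means of plasma cell genes (7.28), immunoglobulin constant genes (8.35), the unfolded protein response (7.38), type I interferon genes (6.45) and NK cell markers (4.02). Wild type 1 was high for Uhrf1 (6.08), Cenpf (5.00), Ebp (6.50) and Xist (9.77) and low for Uty (2.39), Kdm5d (3.11), Eif2s3y (2.06) and the mean of Y-linked genes (2.52). Knockout 3 stood at 10.71 for Ndufa4, 8.09 for Srebf2 and 6.69 for the mean of cell cycle inhibitors.

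Arrays numbered 1 and 2 of both genotypes lay apart from arrays 3 to 5 on the first principal component, which held 38.7% of the variance, at −58.2 to −10.4 against 17.5 to 26.6. RNA of other splenic cells stays open as a candidate explanation: the 10 brightest markers of neutrophils, T cells and erythroid cells had median differences of 3.08, 2.40 and 1.13, the lowest of which is 1.13. The sort kept cells carrying CD19, but how pure the sorted cells were was not tested. Sex of the mice stays open, since wild type 2 is the only 1 of the 4 with high Y-linked signal, and it lay 2.78 log2 units above the highest of arrays 3 to 5 in the neutrophil mean. Longer handling of the cells before lysis stays open too: 3 of the 4 arrays had an immediate early list mean below the median of arrays 3 to 5, but wild type 2 was the highest of all 10 at 7.27, and the mean difference was −0.12 (95% interval −0.47 to 0.22). A different amplification or sort day was not tested, because the labels give none.

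The higher signal of cell cycle G2/M genes in knockout arrays was found in all 5 pairs, with a difference of 0.42 (95% interval −0.68 to 1.52, and −0.051 to 0.89 with the replicate number as a block) and an exact sign-flip p of 0.0625, the smallest that 5 pairs allow. The exact two-sided permutation test of the list mean, which ignores the pairs, gave p = 0.325 (adjusted p = 0.872). With the sex covariate the G2/M difference was 0.18. Cycling plasma cell or erythroid precursors cannot be told apart from a genotype effect, because with both list means as covariates the difference was 0.51 (−0.79 to 1.82) without the block and 0.063 (−0.49 to 0.62) with it, where 2 residual degrees of freedom remain. Erythroid and platelet markers were lower in knockout in all 5 pairs, by 0.055 to 0.87, and the 6 erythroid genes of the list in 4 of 5. That is the opposite of what erythroid precursors would need, but the intervals of the paired mean include 0 (−0.72 to 0.086 for the list, −0.43 to 0.019 for its 6 erythroid genes). Of the 11 list genes 8 were lower and 3 higher, the erythroid gene Epb42 among these at 0.37. Whether arrays numbered 1 and 2 alone carry the G2/M difference also stays open. In arrays 3 to 5 it was 0.22, and the exact permutation p was 0.20, where 3 against 3 allows no less than 0.10. An effect of genotype was not tested apart from these and stays open.

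Flanking DNA of another mouse strain around the targeted allele may account for some of the genes near Zbtb32, such as Cep89 and Gmfg. The odds ratio of 2.37 had an interval of 0.753 to 5.72, so at that unadjusted threshold the test cannot decide, whereas the blocked fit gave 3.14 (1.53 to 5.80). Loss of Zbtb32 acting on nearby genes would give the same pattern and was not tested. If the wild type matches the probes, a probe mismatch in the flanking strain would lower the signal. Gmfg at 0.48 and Pepd at 0.93 go the other way. Whether the wild type matches them is not known here, so a mismatch was not tested for any of the 5 genes.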

How the results depend on the processing

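Arrays 3 to 5 alone, numbers 1 and 2 against 3 to 5 as a covariate, an estimated correlation in arrays 3 to 5 or with the replicate block, and unadjusted thresholds near Zbtb32 were chosen after the result was seen, the p of 0.01 before the neighbours were counted. The direction of the Zbtb32 difference held under every alternative, and its call did not. The number of genes past the threshold, 1 as reported, was 2 without an intensity trend, with array weights and among genes brighter than the median (Zbtb32 and Pmm2), and 2 with the non-B cell covariate (Zbtb32 and Ifi208). It was 0 with each array centred on its median, over all rows of the table, with the replicate block, with the sex, plasma cell or immediate early covariate, and with numbers 1 and 2 against 3 to 5 as a covariate. In these fits Zbtb32 differed by −2.69, −2.73, −2.73, −2.73, −2.74, −2.70 and −2.73, at adjusted p of 0.0540, 0.116, 0.188, 0.118, 0.0725, 0.158 and 0.0505. Leaving out 1 array gave 0 to 1 genes and differences of −2.94 to −2.47. The number of lists, 10 as reported, was 6 after a second quantile normalization, with median centring, without the dimmest genes and with the sex covariate. It was 4 among genes brighter than the median, 5 with the immediate early covariate, 16 at an adjusted p of 0.1, 16 in arrays 3 to 5, and 19 with the replicate block and with the non-B cell covariate. It was 0 with fry (1 list at an unadjusted p of 0.05) and with an estimated correlation in all arrays, in arrays 3 to 5 or with the replicate block. Leaving out 1 array gave 3 (without wild type 4) to 19 lists (without wild type 2). Genes near Zbtb32 numbered 5 and 20 at unadjusted p of 0.01 and 0.05, 8 in arrays 3 to 5 and 11 with the replicate block. No list of the 10 changed direction. Sign changes were seen for genes that never passed: Gabarapl2 (−0.0023 with the mean of its rows), Ighm (−0.067 with the sex and −0.089 with the plasma cell covariate, −0.21 to 0.46 leaving out 1 array), Kdm5d (0.038 with the sex covariate, 0.054 in arrays 3 to 5, −1.38 to 0.016 leaving out 1 array), Xist (−0.35 in arrays 3 to 5), Cd6 (−0.47 to 0.0035) and Uty (−1.39 to 0.017). The sex covariate is the mean of the Y-linked genes minus Xist, so it contains Kdm5d and its value there says nothing of genotype. Kdm5d changed sign without knockout 1 and Uty without knockout 2, arrays with high Xist and low Y-linked signal. Arrays 3 to 5 hold no array with high Xist. The cause of the other changes was not tested. The replicate block changed no other gene's call.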

Other observations

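Genes outside the fixed rule were looked at after their values were seen. Ifi208, an interferon-inducible gene, differed by 1.13 in all 10 arrays and by 1.13 in arrays 3 to 5, with the same direction in 5 of 5 pairs, at a limma adjusted p of 0.953. Dusp10, a MAP kinase phosphatase, differed by 0.85 and by 1.00 in arrays 3 to 5. The mitochondrially encoded ND3 differed by 0.59 and by 0.62, at an adjusted p of 0.0835 in arrays 3 to 5. Lgals4, a galectin, differed by −1.02 in arrays 3 to 5. None of these passed in either fit, and Ifi208 passed with the non-B cell covariate.

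Other splits of the 10 arrays bear on the counts. Of 100 splits into 5 and 5, 6 gave at least 1 gene, the real one included, and the highest other count was also 1, so chance cannot be excluded for the count of 1 gene. For lists, 47 of the 100 splits gave at least the real count of 10, with a highest other count of 23, so chance cannot be excluded there either. Of the 4 drawn splits that put all 4 arrays numbered 1 and 2 on one side, 3 gave 1 gene and 19 to 21 lists, and 1 gave 0 genes and 15 lists. Over all splits but the real one the median was 9 lists. The highest count, 23, came from a split with 3 of these arrays on one side. That structure of the arrays stays a candidate source of such counts. With the replicate number as a block the real split gave 0 genes and 19 lists. Among the 16 splits that part all 5 pairs, fitted with the replicate block, the real split gave 19 lists and the highest other 13, and both gave 0 genes. Without the block it gave 1 gene and 10 lists, where the highest other counts were 0 genes and 10 lists, so that 2 of the 16 splits reached 10 lists. The others mix the genotypes within each side. These 16 splits are too few for a share under 0.05.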
